A study of Mus musculus with 6 samples.

How the data were processed

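Whole pancreas was dissected from mouse embryos at e16.5 and total RNA was sequenced from 6 samples, 3 labelled Neurog3:cre (here control) and 3 labelled Neurog3:cre with RARdnfl/fl (here RARdn). The deposited values were raw read counts per gene, 1 table per sample, with 54735 gene symbols and 5 summary lines in the layout that HTSeq writes. Per the submitters' processing notes, FastQC, cutadapt, HISAT2, HTSeq, bedtools and DESeq2 were used and the genome builds were mm10 and GRCm38. Their versions, the gene annotation, the strand setting of the counting and any filter on reads are not given in the sources used here. Per the labels' protocols, RNA was extracted with an RNeasy Mini kit and libraries followed standard Illumina protocols, with no statement of how ribosomal RNA was removed. Reads of overlapping or antisense genes cannot be told apart when the strand setting is unknown, and reads of near-identical copies can be lost or split. Among the genes named, these overlap another annotated gene and carry this doubt: Rara, Rarb, Iapp, Ghrl, Neurog3, Hist1h2al, Pzp, Stra6, Rps2, CT010467.1, Malat1, BC002163, Muc4, Pam, Cbfa2t3, Glp1r, Ctrb1, Krt8, Notch1, Axin2, Mki67, Top2a, Jun, Ramp2, Cdh5, Csf1r, Vil1, Ahsg, Erbb3, Gt(ROSA)26Sor, Xist, Ddx3y, Bcat1 and Plbd1.

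The 5 summary lines were kept out of library sizes and tests. Of all reads, the control libraries had 8.49% ± 0.776 (SD, n = 3) outside genes, 5.44% ± 0.0581 in more than 1 gene, 1.65% ± 0.0139 of low alignment quality, 3.32% ± 0.0761 not aligned and 12.1% ± 0.434 not uniquely aligned. The RARdn libraries had 4.34% ± 1.27, 4.93% ± 0.0546, 1.57% ± 0.102, 2.41% ± 0.111 and 13.9% ± 2.51 in the same classes. Gene types, positions, GC content and lengths were taken from GENCODE release M21 for GRCm38, which held 54183 of the symbols, and 99.6% of the genes tested had a GC content and a length.

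Genes were tested with edgeR 4.0.16 in R 4.3.3: low genes were removed with filterByExpr and the group, libraries were scaled with TMM, and RARdn was compared with control by the quasi-likelihood test (glmQLFit and glmQLFTest, 2-sided) with genotype as the only term. The p-values were adjusted over the 19070 genes tested by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Levels are edgeR's CPM after TMM scaling, given as mean ± SD over 3 libraries, and log2 fold changes are RARdn over control with approximate standard errors (SE). The test gives no SE, so each was worked back as the absolute log2 fold change over the square root of the test's F statistic. All adjusted p-values of single genes come from this edgeR test unless another tool is named. Labels do not say whether embryos shared a litter, a day or a batch, so p-values measure the spread between these samples, which may partly be technical. The description fields of RARdn 2 and 3 open with the same number and that of RARdn 1 with another, and the labels do not explain these numbers.

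Gene lists were fixed before the data were examined: 26 lists for islet cell types, endocrine progenitors, acinar and duct cells, retinoic acid, Notch and Wnt signalling, proliferation, stress and the other cell types that a pancreas dissection can hold. Of 459 list entries, 458 matched a symbol in the tables. The 23 lists with at least 4 tested genes, other than the sex-linked and mitochondrial lists, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 23 lists, and again with an estimated correlation and with fry. With scaling to the pan-endocrine list only fry was used, adjusted over the endocrine progenitor, beta cell, alpha cell and other islet hormone lists alone. 4 genes (Dll1, Hes1, Mfng and Rbp4) stood in 2 lists each. The hormone genes Ins1, Ins2, Iapp, Gcg, Sst, Ppy, Pyy and Ghrl and the progenitor gene Neurog3 were also adjusted over their own list of 9.

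The rule for naming genes was fixed at the same time. Rara, Rarb, Rarg and the 9 hormone and progenitor genes were always named. To these were added the 8 largest increases and the 8 largest decreases among called genes with a mean of at least 2 CPM and no overlap between groups, leaving out predicted genes and the sex-linked and mitochondrial lists, and for each list up to 4 called members in order of p, filled up to 2 with the most abundant members. Genes outside this rule are said to have been chosen after their values were seen. The result of 1 gene that the rule includes is not reported here. An exploratory run of the same gene and list tests, with its largest changes by gene type and chromosome, was looked at before the added alternatives and the tests of explanations were chosen.

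The test was tested on simulated data. Counts were negative binomial with the library sizes of these samples, each gene's mean over them and the dispersion of the fitted trend. Of 18656 simulated genes tested, 27.3% of those changed by 1.5-fold, 58.5% of those changed by 2-fold and 96.9% of those changed by 4-fold were recovered, and 5 of 124 calls were false. Dispersions of single genes were not simulated, nor was a spread that differs between the groups, as for Sst (SD 11.5 CPM in controls and 156 CPM in RARdn). These rates therefore do not show how often the gene test errs in these data. In a further simulation of the same kind camera found a list of 20 genes shifted by 1.5-fold and did not find 1 unshifted list of 20. Simulated genes varied independently. The estimated correlations of the real lists ranged from -0.036 (genes that make, carry or sense retinoic acid) to 0.888 (mesothelium). The simulation therefore does not show how often camera errs in these data.

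Alternatives fixed beforehand were RLE and upper-quartile scaling, no filter on low counts, a filter of at least 1 CPM in 3 libraries, library sizes without the acinar list, the replicate number as a block, leaving out each library, robust dispersions, a test against a fold of 1.2 (glmTreat), leaving out the sex-linked list, thresholds of 0.1 and 0.01, DESeq2 1.42.0, limma-voom, and scaling to the pan-endocrine list. An analysis of protein-coding genes only, a correction for GC content and length, and a term for libraries with Xist were added after the data had been examined. Control 1 and 3 had Xist, so with this term the genotype effect rests on control 2 alone against the 3 RARdn libraries. Shares of reads were compared by 2-sided exact permutation tests, in which 3 against 3 libraries cannot give a p below 0.1. The 95% Wilson intervals of shares in single libraries reached at most 0.015 percentage points to either side, which covers counting error only.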

Results

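Pancreata of mouse embryos at e16.5 were profiled by RNA sequencing to ask how retinoic acid signalling in endocrine progenitors bears on the specification of islet cells. Neurog3 is the transcription factor gene that marks endocrine progenitors, and its cre driver was present in all 6 samples. The 3 control samples carried the driver alone, and the 3 RARdn samples also carried the RARdn allele in the floxed, homozygous form that the labels name RARdnfl/fl. The letters are the usual short form of a dominant-negative retinoic acid receptor, although the labels do not spell them out. The background was a C57Bl6 and 129SV mixture in both groups. Counts in genes were 38572573, 44735721 and 44334558 in control 1, 2 and 3, and 47926773, 52015498 and 35256531 in RARdn 1, 2 and 3. At least 1 count was seen for 28328, 28517 and 27828 genes in the controls and for 27147, 26437 and 23995 genes in the RARdn libraries.

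Transcripts of the receptor genes were read first, because the allele bears the receptor's name. Rara (chromosome 11, 98927818 to 98974942, GRCm38) rose from 32.8 ± 1.29 CPM in controls to 45.7 ± 1.70 CPM in RARdn pancreas (log2 fold change 0.48, SE 0.089, adjusted p = 0.0256). Rarg (chromosome 15, 102234938 to 102257517) rose from 18.9 ± 1.44 to 26.9 ± 2.02 CPM (0.51, SE 0.11, adjusted p = 0.0438). Rarb, itself a textbook target of retinoic acid, was at 2.77 ± 0.575 and 2.57 ± 0.686 CPM (adjusted p = 0.870). The labels give no sequence of the allele, so these counts do not check the genotype. For the same reason, reads of the allele cannot be told apart from reads of the receptor genes. Transcripts of Xist, made from the inactive X chromosome, were at 1158 and 1118 CPM in control 1 and 3 and at or below 0.312 CPM in the other libraries. Ddx3y, on the Y chromosome, was at 0 in control 1 and 3, at 49.8 CPM in control 2 and at 47.3 to 50.7 CPM in the RARdn libraries, so the sexes were not balanced between the groups.

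The libraries separated by group. The groups also did not overlap in the shares of ribosomal RNA genes and of reads outside genes (given below), so this separation cannot be assigned to genotype alone. The first principal component of log2 CPM held 50.5% of the variance and placed all controls between -48.3 and -45.2 and all RARdn libraries between 44.8 and 48.8. The second, with 20.7%, spread the RARdn libraries from -56.1 to 45.5 while the controls lay between -8.62 and 6.59. Spearman correlations were 0.979 to 0.992 within groups and 0.972 to 0.979 between groups. Pairs within a group differed by more than counting noise (lowest chi-square per degree of freedom 15.6), so no table was a copy of another, which does not show that the samples were independent.

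Composition differed between the groups in part. Ribosomal RNA genes took 0.930% ± 0.0260 of the counts in controls and 0.0756% ± 0.00549 in RARdn libraries. Reads outside genes took 8.49% ± 0.776 and 4.34% ± 1.27 of all reads (2-sided exact permutation p = 0.1 for both shares, the smallest that 3 against 3 allows). Digestive enzyme and other acinar genes took 19.1% ± 0.756 of the counts in controls but 7.61%, 23.0% and 27.8% in RARdn 1, 2 and 3 (exact permutation p = 1). The mitochondrial list took 2.40% ± 0.0551 in controls and 5.23%, 4.54% and 2.38% in RARdn 1, 2 and 3 (exact permutation p = 0.3).

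**Figure D1:**
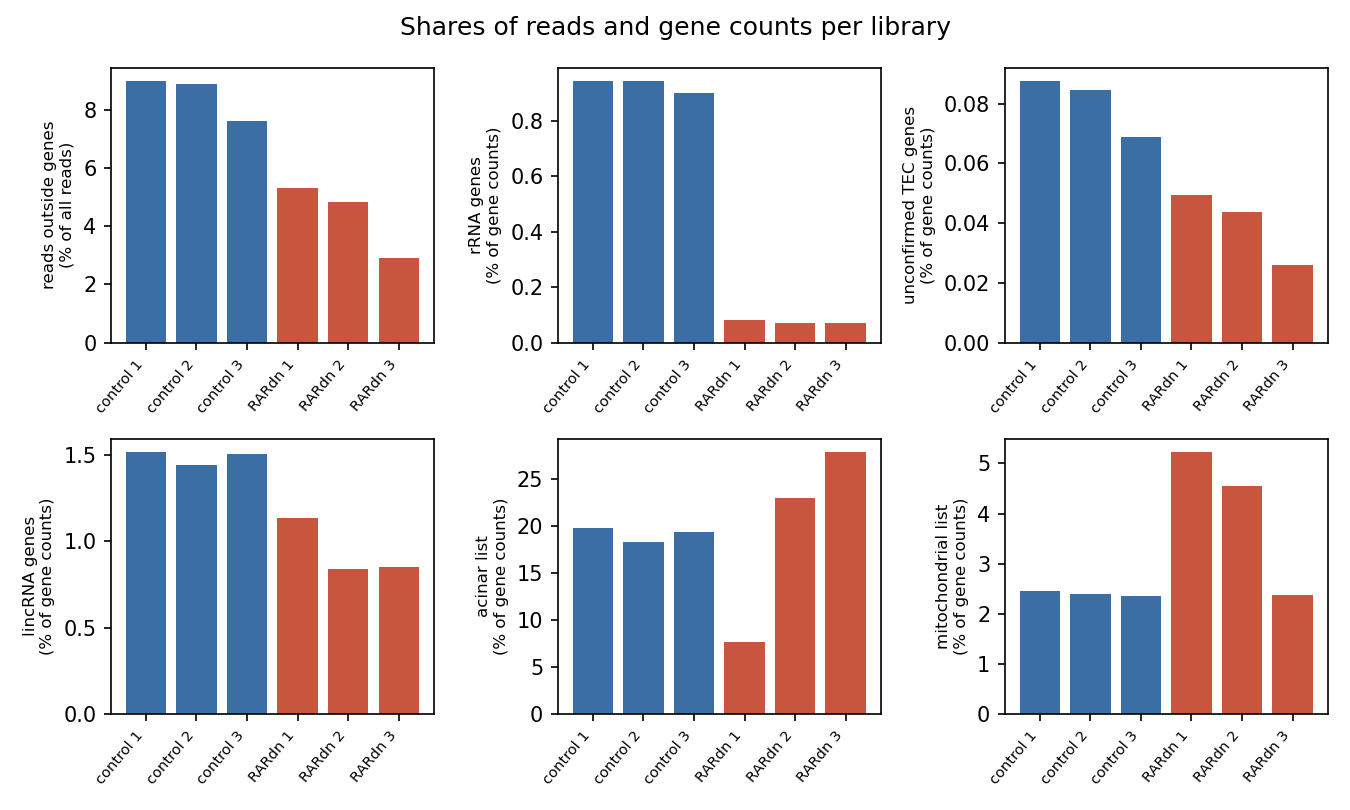
Bars give, for each of the 6 libraries, the percent of all reads that fell outside genes and the percent of gene counts in ribosomal RNA genes, TEC genes (transcripts of the annotation that still await an experimental check), lincRNA genes, the acinar list and the mitochondrial list. Ribosomal RNA genes took 0.0718% to 0.0819% in RARdn libraries and 0.900% to 0.946% in controls, and the acinar share ranged from 7.61% to 27.8% among RARdn libraries.

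The comparison of RARdn with control pancreas asked first which islet hormones differed. Sst, the hormone gene of delta cells (chromosome 16, 23889573 to 23890958), rose from 104 ± 11.5 to 394 ± 156 CPM, a 3.78-fold difference (log2 1.92, SE 0.27, adjusted p = 0.0129). It was higher in 3 of 3 RARdn libraries than in any control. Ins2 (chromosome 7, 142678656 to 142743381), 1 of the 2 mouse insulin genes, fell from 1205 ± 171 to 669 ± 95.4 CPM (log2 -0.85, SE 0.18, adjusted p = 0.0431). Pyy, encoding peptide YY (chromosome 11, 102106676 to 102107832), fell from 139 ± 19.1 to 84.0 ± 17.3 CPM (log2 -0.73, SE 0.17, adjusted p = 0.0482). Ins1 (chromosome 19, 52264297 to 52265476) was at 572 ± 82.6 and 379 ± 42.8 CPM and did not pass over all genes (adjusted p = 0.0832), but did when adjusted over the list alone (adjusted p = 0.0137, edgeR). The glucagon gene Gcg, the mark of alpha cells (chromosome 2, 62474530 to 62483650), was at 825 ± 132 and 868 ± 180 CPM (log2 0.07, SE 0.21, adjusted p = 0.870).

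Of the 9 hormone and progenitor genes, 3 passed over all genes tested and 4 passed when adjusted over the list alone. The 5 others were Iapp (194 ± 4.93 and 223 ± 63.6 CPM, adjusted p = 0.583), Ppy (15.99 ± 1.67 and 18.96 ± 13.4 CPM, adjusted p = 0.777), Ghrl (10.3 ± 0.915 and 11.9 ± 5.35 CPM, adjusted p = 0.705), Gcg and Neurog3 (37.7 ± 8.19 and 29.1 ± 8.79 CPM, adjusted p = 0.361). Scaled to the pan-endocrine list, Neurog3 and Ins1 were called lower (log2 -0.67 and -0.88, adjusted p = 0.0438 and 0.0175), and DESeq2 called Ins1 lower (adjusted p = 0.00319). Neurog3, Iapp and Ghrl overlap genes on the other strand and are uncertain for that reason. Ratios within a library do not depend on how much of the tissue was endocrine. Sst per insulin count (Ins1 plus Ins2) was 0.0589 ± 0.00390 in controls and 0.386 ± 0.169 in RARdn libraries, and Gcg per insulin count was 0.475 ± 0.132 and 0.830 ± 0.157. Sst per Gcg count was 0.129 ± 0.0240 and 0.457 ± 0.154, and none of the 3 ratios overlapped between groups (2-sided exact permutation p = 0.1 for each, the smallest possible). Sst kept its call without control 1, control 3 or any 1 RARdn library and not without control 2 (log2 1.87, adjusted p = 0.0580) or with a term for Xist (log2 2.01, adjusted p = 0.131; its range over 18 alternatives was 5.06e-12 to 0.131). Ins2 was not called without control 1, 2 or 3 or RARdn 2 (adjusted p = 0.114, 0.163, 0.0930 and 0.113). Pyy was not called without control 1, 2 or 3 or RARdn 1 or 2 (0.123, 0.180, 0.0680, 0.0742 and 0.0521).

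**Figure D2:**
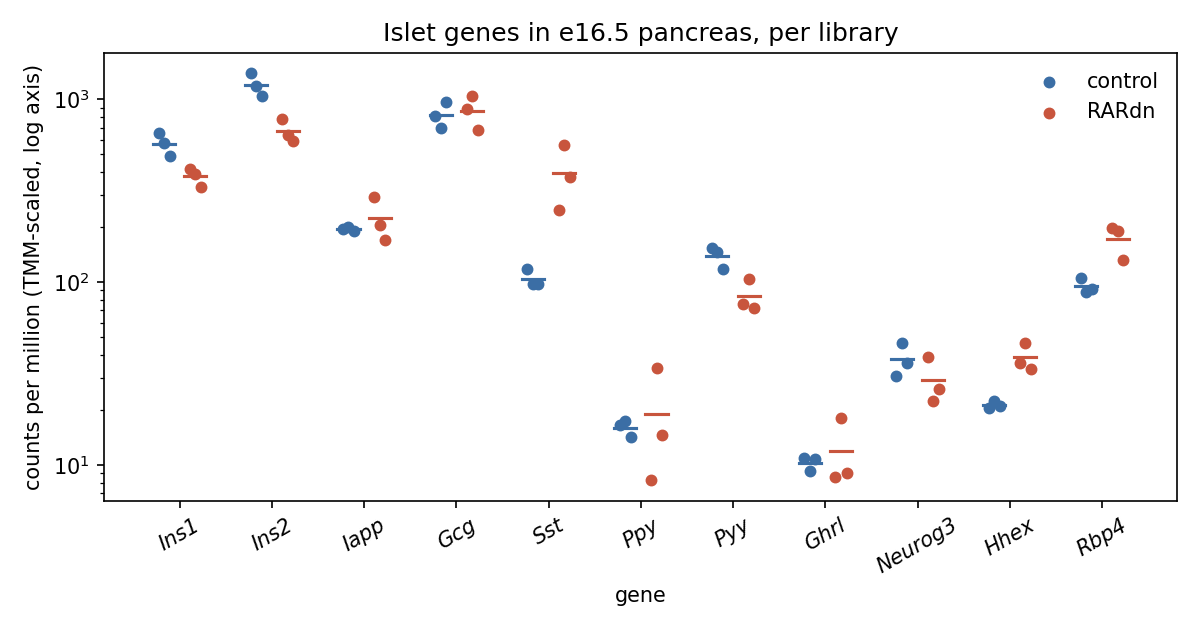
Each point is 1 library (3 per group) and each bar the group mean, in TMM-scaled CPM on a log axis, for 9 hormone and progenitor genes and for Hhex and Rbp4. Sst lay at 97.2 to 118 CPM in controls and at 248 to 559 CPM in RARdn libraries, while Gcg overlapped between the groups.

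In the list of other islet hormone genes, 3 of 10 rose and 1 fell over all genes, and 5 rose and 1 fell when adjusted over the list alone. Besides Sst and Pyy, 1 was Hhex, a transcription factor that delta cells require (chromosome 19, 37434810 to 37440731; 21.3 ± 0.897 and 38.7 ± 6.83 CPM, log2 0.86, SE 0.13, adjusted p = 0.0160). The other was Rbp4, a retinol-binding protein gene that delta cells express (94.9 ± 8.91 and 173 ± 35.7 CPM, log2 0.87, SE 0.16, adjusted p = 0.0279). The list passed camera as higher (median log2 0.51, adjusted p = 0.00235), with adjusted p = 0.722 with an estimated correlation and, by fry with scaling to the pan-endocrine list, 0.373. Hhex and Rbp4 are also expressed in liver. Hhex was at 36.0, 46.4 and 33.6 CPM and Rbp4 at 197, 189 and 132 CPM in RARdn 1, 2 and 3, where the liver gene Alb was at 597, 137 and 3.19 CPM. Hhex was not called without control 1, 2 or 3 (adjusted p = 0.0532, 0.0597 and 0.0557). Rbp4 was not called without control 1, 2 or 3 or RARdn 2 (0.0596, 0.141, 0.108 and 0.0867).

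Of 27 beta cell genes, 2 fell and none rose over all genes, 6 fell when adjusted over the list alone, and 22 had a log2 fold change below 0. Besides Ins2 the called gene was Glp1r, the receptor for glucagon-like peptide 1, at 2.18 ± 0.467 and 0.627 ± 0.292 CPM (log2 -1.76, SE 0.39, adjusted p = 0.0456). The list passed camera as lower (median log2 -0.36, adjusted p = 0.00216), with adjusted p = 0.722 with an estimated correlation and 0.292 by fry. Scaled to the pan-endocrine list it passed fry as lower, as the alpha cell list did. Relative to the control mean, the list median lay at -0.0133, -0.593 and -0.662 log2 units in RARdn 1, 2 and 3, where that of the acinar list lay at -1.53, 0.634 and 0.645. Glp1r was not called without any 1 library except RARdn 3 (adjusted p from 0.0547 without RARdn 1 to 0.172 without control 2).

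Alpha cell genes went both ways. The list of 15 did not pass camera (median log2 -0.14, adjusted p = 0.631), and 7 of its genes had a log2 fold change above 0 and 8 below. Gcg, its most abundant named member, was at 825 ± 132 and 868 ± 180 CPM (adjusted p = 0.870). In RARdn 1, 2 and 3 the list median lay at 0.0556, -0.244 and -0.123 log2 units relative to the control mean. Scaled to the pan-endocrine list, it passed fry as lower (adjusted p = 0.0155 over the lists so tested), against 0.444 by fry without that scaling. The scaling itself moved genes down, as Gcg went from log2 0.07 to -0.2155.

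The median of genes of the secretory machinery common to endocrine cells lay at 0.469, 0.218 and -0.0897 log2 units relative to the control mean in RARdn 1, 2 and 3. Of 30 pan-endocrine genes, 2 rose over all genes: Vgf, a secretory granule protein gene (2.10 ± 0.334 and 7.63 ± 2.29 CPM, log2 1.87, SE 0.26, adjusted p = 0.0123), and Pam, the enzyme that amidates peptide hormones (127 ± 1.30 and 202 ± 11.96 CPM, log2 0.68, SE 0.11, adjusted p = 0.0160). Adjusted over the list alone, 8 rose and 1 fell. The list passed camera (median log2 0.27, adjusted p = 0.00608), with adjusted p = 0.722 with an estimated correlation, and did not pass without RARdn 1 (adjusted p = 0.116), the library with the lowest acinar share, or with the Xist term (0.0560). Vgf was not called without control 2 (adjusted p = 0.0563). Pam was not called without control 1, 2 or 3 or RARdn 2 (0.0558, 0.106, 0.0643 and 0.0600). None of 23 endocrine progenitor genes was called by edgeR, where 3 had an unadjusted p under 0.05 and DESeq2 called 0. Their median log2 fold change was 0.05, their mean -0.0011, and camera gave adjusted p = 0.868. The most abundant, Amotl2 and Cbfa2t3, had log2 fold changes of 0.17 (adjusted p = 0.398) and -0.0025 (adjusted p = 0.995).

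Genes that make, carry or sense retinoic acid were partly higher. Of 15 such genes, 4 rose, both over all genes and adjusted over the list alone: Rara, Rarg, Rbp4 and Aldh1a3, a retinaldehyde dehydrogenase gene that makes retinoic acid (0.482 ± 0.185 and 1.96 ± 0.287 CPM, log2 2.01, SE 0.34, adjusted p = 0.0194). Whether reads of the allele were counted for Rara or Rarg is not known, and the list tests carry this doubt too. The list of these 15 genes did not pass camera (median log2 0.08, adjusted p = 0.0506) but did without control 1, RARdn 1 or RARdn 2 (adjusted p = 0.0463, 0.0375 and 0.0350), with RLE scaling (0.0492), without a filter on low counts (0.00488) or without the acinar genes (0.0448). Its adjusted p was 0.722 with an estimated correlation and 0.0490 with fry, which asks only whether the genes move one way on balance. Of 18 retinoic acid target genes, 1 rose over all genes and over the list alone: Stra6, the membrane receptor for retinol-binding protein (chromosome 9, 58063788 to 58153996), at 7.56 ± 1.76 CPM in controls and 15.7, 40.3 and 117 CPM in RARdn 1, 2 and 3 (log2 2.93, SE 0.63, adjusted p = 0.0418). Stra6 overlaps Ccdc33 and Gm16131. Meis2, the most abundant target, was at 134 ± 5.38 and 137 ± 12.8 CPM (adjusted p = 0.903). The list did not pass camera (median log2 0.14, adjusted p = 0.0791) but did without control 1, RARdn 1 or RARdn 3 (adjusted p = 0.0208, 0.0456 and 0.0471), without a filter on low counts (0.0102), with the replicate block (0.0420) or with the Xist term (0.0361). Stra6, Aldh1a3, Rara, Rarg and Rbp4 were each not called without control 1, 2 or 3 or RARdn 2, with adjusted p from 0.0518 for Aldh1a3 without control 2 to 0.201 for Rarg without control 2. Rarg was also not called without RARdn 1 (adjusted p = 0.0559). With protein-coding genes alone none of these genes was called. GC content and length correction ended the calls of Rara and Rarg, the replicate block that of Rarg, and limma-voom and robust dispersions that of Stra6.

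Of 24 Wnt genes, 4 rose over all genes and 11 rose when adjusted over the list alone, and none fell. Examples were Axin2, a feedback target of canonical Wnt signalling (15.0 ± 0.638 and 22.5 ± 1.998 CPM, log2 0.58, SE 0.11, adjusted p = 0.0312), the receptor genes Fzd7 (log2 0.62, adjusted p = 0.0448) and Fzd1 (0.77, adjusted p = 0.0452), and the planar polarity gene Prickle1 (0.54, adjusted p = 0.0453). The Wnt list passed camera (median log2 0.43, adjusted p = 6.82e-05), with adjusted p = 0.722 with an estimated correlation. Its median lay at 0.576, 0.496 and 0.226 in RARdn 1, 2 and 3, where that of the mesenchyme list lay at 0.495, 0.663 and 0.461. Of 17 Notch genes, 1 rose over all genes and 3 when adjusted over the list alone. The called gene was Dtx1, a ubiquitin ligase gene of the pathway (3.67 ± 0.460 and 7.52 ± 0.971 CPM, log2 1.04, SE 0.18, adjusted p = 0.0212), while Notch1 was at 154 ± 28.2 and 146 ± 18.3 CPM (adjusted p = 0.813). The Notch list passed camera (median log2 0.21, adjusted p = 0.0276), with adjusted p = 0.722 with an estimated correlation. It did not pass without RARdn 1 (adjusted p = 0.116), with GC content and length correction (0.267), with at least 1 CPM in 3 libraries (0.05205) or with the Xist term (0.0981), and 5 of its genes had a log2 fold change below 0. None of the 4 Wnt genes was called without control 1, 2 or 3 or RARdn 2, and only Axin2 was called without RARdn 1, with adjusted p up to 0.202 for Prickle1 without control 2. With protein-coding genes alone none of the 4 was called, and with GC content and length correction only Prickle1 was. Dtx1 was not called without control 2, control 3 or RARdn 2 (0.111, 0.0815 and 0.0765).

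**Figure D3:**
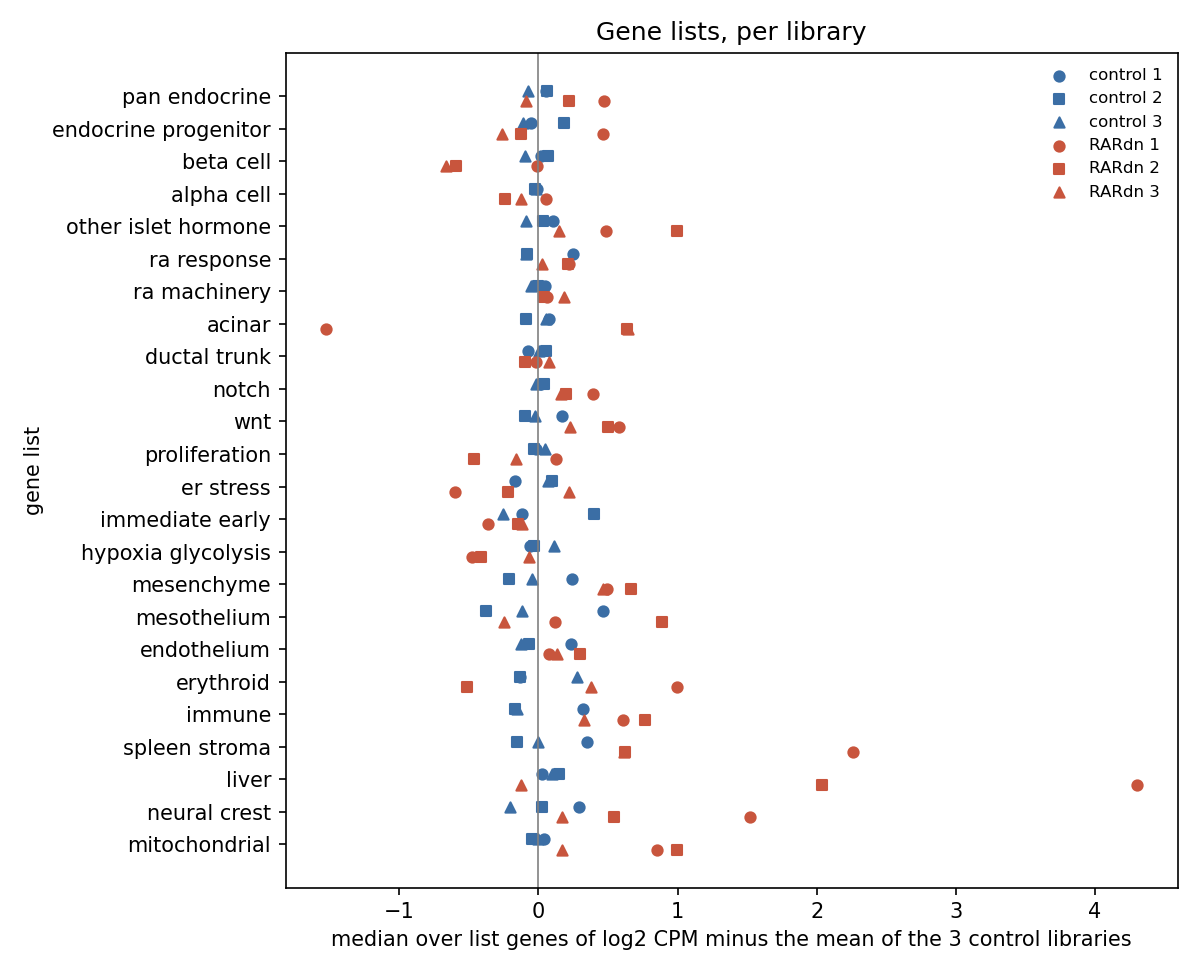
Each point is the median over the genes of a list of log2 CPM minus the mean of the 3 control libraries, with 1 symbol per library. Beta cell genes lay at -0.0133, -0.593 and -0.662 in RARdn 1, 2 and 3 and Wnt genes at 0.576, 0.496 and 0.226, while liver genes lay at 4.30, 2.04 and -0.126.

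Cell cycle genes lay lower in RARdn 2 and 3 and not in RARdn 1, with list medians of -0.461, -0.164 and 0.129 log2 units relative to the control mean. None of 25 proliferation genes was called by edgeR, where 4 had an unadjusted p under 0.05, all below 0, and DESeq2 called 3 and limma-voom 1. The list passed camera as lower (median log2 -0.15, adjusted p = 0.0271), with adjusted p = 0.881 with an estimated correlation. It did not pass without control 3, RARdn 2 or RARdn 3 (adjusted p = 0.144, 0.869 and 0.0708). Nor did it pass with GC content and length correction (0.0572), without a filter on low counts (0.0561) or with the Xist term (0.121). Mki67 was at 490 ± 19.8 and 285 ± 69.9 CPM (log2 -0.78, adjusted p = 0.0539) and Top2a at 281 ± 16.1 and 197 ± 44.1 CPM (-0.52, adjusted p = 0.130). Mki67 was called without RARdn 1 or RARdn 3 (adjusted p = 0.0214 and 0.0441), with robust dispersions (0.0451), without a filter on low counts (0.0125), by limma-voom (0.0401) and by DESeq2 (0.000822), which also called Top2a (0.0483). Genes of endoplasmic reticulum stress, immediate early genes and genes of hypoxia and glycolysis did not pass camera (adjusted p = 0.564, 0.580 and 0.0791). edgeR called none of their 16, 15 and 16 genes, where 4, 5 and 5 had an unadjusted p under 0.05 and DESeq2 called 0, 2 and 1. Hspa5 and Sel1l, Btg2 and Jun, and Ldha and Eno1, the most abundant of each, had adjusted p from 0.158 for Eno1 (log2 -0.72) to 0.707 for Jun (log2 0.15). Without RARdn 3 the stress and hypoxia lists passed camera (adjusted p = 0.00961 and 0.000482), as the hypoxia list did without control 1 (0.0458), and Hspa5, Btg2, Ldha and Eno1 were called (adjusted p = 0.0334, 0.0340, 0.0158 and 0.00789). The immediate early list passed as lower with the Xist term, but that term sets control 2 alone against the RARdn libraries. Relative to the control mean, its median was 0.399 log2 units in control 2 and -0.122 and -0.252 in control 1 and 3. In RARdn 1, 2 and 3 it was -0.363, -0.147 and -0.12. The hypoxia list passed as lower with at least 1 CPM in 3 libraries (adjusted p = 0.0436), the replicate block (0.0223) and protein-coding genes alone (0.0164).

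In the exocrine tissue, edgeR called none of 38 acinar genes, where 2 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 0. It called 12 of them without RARdn 1 and 3 without RARdn 3. edgeR called none of 22 duct and trunk genes, where 5 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 1. The most abundant acinar genes, Ctrb1 and Pnliprp1, were at 62177 ± 3600 and 49312 ± 1387 CPM in controls, and at 16568 to 93376 and 15969 to 73544 CPM in RARdn libraries. Relative to the control mean, the acinar list median lay at -1.53 log2 units in RARdn 1 and at 0.634 and 0.645 in RARdn 2 and 3. The list did not pass camera (adjusted p = 0.707) except as higher without RARdn 1 (adjusted p = 2.07e-16). Acinar genes have close paralogs, so their single values are uncertain. The duct keratin genes Krt18 and Krt8 were at 599 ± 20.5 and 421 ± 174 CPM and at 570 ± 37.2 and 388 ± 145 CPM (adjusted p = 0.292 and 0.222). Both were called without RARdn 3 (adjusted p = 0.0133 and 0.0111). The duct list had a median log2 fold change of -0.06, a mean of 0.05 and adjusted p = 0.828 by camera, as lower.

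Of 20 mesenchyme genes, 2 rose over all genes and 10 when adjusted over the list alone. The list passed camera (median log2 0.54, adjusted p = 3.03e-06), with adjusted p = 0.722 with an estimated correlation. The 2 were Lum, a collagen-binding proteoglycan gene (52.1 ± 8.41 and 110 ± 16.1 CPM, log2 1.07, SE 0.15, adjusted p = 0.0128), and Acta2, smooth muscle actin (43.9 ± 13.03 and 98.9 ± 30.8 CPM, log2 1.17, SE 0.26, adjusted p = 0.0431). Of 14 immune genes, 1 rose over all genes and 7 when adjusted over the list alone. The list passed camera (median log2 0.65, adjusted p = 0.00185), with adjusted p = 0.722 with an estimated correlation. The called gene was Csf1r, the receptor that macrophages need (30.7 ± 6.30 and 53.9 ± 11.1 CPM, log2 0.81, adjusted p = 0.0454), while C1qa was at 258 ± 51.0 and 211 ± 113 CPM (adjusted p = 0.667). Of 15 endothelial genes, Ramp2 rose (28.8 ± 5.05 and 43.7 ± 3.52 CPM, log2 0.60, adjusted p = 0.0480), 2 rose when adjusted over the list alone, Cdh5 was at 167 ± 9.29 and 167 ± 14.6 CPM. The list did not pass camera (median log2 0.13, adjusted p = 0.0938) but did without control 1 or RARdn 1 (adjusted p = 0.00508 and 0.0456), without a filter on low counts (0.00983) or with the Xist term (0.0362). Lum was not called without control 2 (adjusted p = 0.0587). Acta2, Csf1r and Ramp2 were not called without control 2, control 3 or RARdn 2 (adjusted p from 0.105 for Acta2 without RARdn 2 to 0.197 for Ramp2 without control 2).

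Neural crest genes passed camera as higher (13 genes, median log2 1.01, adjusted p = 0.0168), with adjusted p = 0.722 with an estimated correlation. It did not pass without RARdn 1 (adjusted p = 0.296) or with the Xist term (0.0560). Their only called member went the other way: Ret, the GDNF receptor gene of enteric nerves (chromosome 6, 118151745 to 118197718), fell from 139 ± 17.5 to 61.2 ± 16.9 CPM (log2 -1.18, SE 0.20, adjusted p = 0.0202). It was not called without control 2 or control 3 (adjusted p = 0.0800 and 0.0655). Adjusted over the list alone, 5 of them rose and 1 fell, and Erbb3 was at 62.9 ± 9.87 and 60.2 ± 10.02 CPM (adjusted p = 0.850). Relative to the control mean, the neural crest median lay at 1.52, 0.542 and 0.166 log2 units in RARdn 1, 2 and 3. In control 1, 2 and 3 it lay at 0.295, 0.0249 and -0.206. The list took 0.0330%, 0.0163% and 0.0164% of the counts in RARdn 1, 2 and 3 and 0.0251% ± 0.00219 in controls. Mesothelial and red blood cell genes did not pass camera (adjusted p = 0.562 and 0.290). edgeR called none of their 8 and 14 genes, where 2 and 3 had an unadjusted p under 0.05 and DESeq2 called 1 and 2. The red blood cell list had a median log2 fold change of 0.13 and a mean of 0.57 and passed camera without RARdn 2 (adjusted p = 0.000286) or a filter on low counts (0.0348). Upk3b and Lrrn4, and Hbb-bs and Hba-a1, the most abundant of each, had log2 fold changes of 0.44 and 0.15, and -0.02 and -0.27 (adjusted p = 0.466, 0.797, 0.967 and 0.624).

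Markers of neighbouring organs were uneven among the RARdn libraries. Of 10 liver genes, Alb and Ahsg, which encode plasma proteins, rose, and when adjusted over the list alone 6 rose and 1 fell. Alb was at 597, 137 and 3.19 CPM in RARdn 1, 2 and 3 against 1.82 ± 0.956 CPM in controls (adjusted p = 0.0428). Ahsg was at 43.5, 24.4 and 0.230 against 0.155 ± 0.146 CPM (adjusted p = 0.0418). The liver list passed camera (median log2 3.02, adjusted p = 0.00518), with adjusted p = 0.722 with an estimated correlation. It did not pass without RARdn 1 (adjusted p = 0.0674) or with at least 1 CPM in 3 libraries (0.0507). Of 6 spleen genes edgeR called none, where 3 had an unadjusted p under 0.05 and DESeq2 called 1, and camera gave adjusted p = 0.220 (0.00600 without a filter on low counts and 0.0240 with the replicate block). The neutrophil genes S100a8 and S100a9 were at 26.3 and 25.5 CPM in RARdn 1 and at 4.76 ± 2.23 and 3.19 ± 1.76 CPM in controls (adjusted p = 0.185 and 0.125 over all libraries). S100a9 was called without RARdn 3 (adjusted p = 0.0383) and with the replicate block (0.0268), and both were called without a filter on low counts (0.0213 for S100a8 and 0.00605 for S100a9). Only 3 of the 14 gut genes were detected well enough to test, and 2 of them fell when adjusted over the list alone. Muc6, a gel-forming mucin of stomach and duct glands, fell from 4.74 ± 0.924 to 0.837 ± 0.556 CPM (log2 -2.44, SE 0.49, adjusted p = 0.0340), and Vil1 was at 55.6 ± 6.13 and 35.6 ± 14.5 CPM (adjusted p = 0.166, and 0.00788 without RARdn 3). All 13 mitochondrial genes had a log2 fold change above 0, with 1 called over all genes and 8 when adjusted over the list alone. Of 5 sex-linked genes Xist was called lower (adjusted p = 0.0350), though not without control 1 or 3 or RARdn 1 or 2 (0.0693, 0.0719, 0.0625 and 0.117). Alb was not called without control 1, 2 or 3 or RARdn 2, Ahsg was not called without any 1 library except RARdn 3, and Muc6 was not called without control 1, 2 or 3 or RARdn 2, with adjusted p from 0.0510 for Ahsg without RARdn 1 to 0.151 for Alb without control 3. The log2 fold change of Ahsg was 7.16 and became 6.29 without RARdn 1 and 8.21 without control 2. Of the 10 liver genes limma-voom called 0.

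Across the genome, 767 of 19070 genes were called, 262 higher and 505 lower in RARdn pancreas, and 4238 had an unadjusted p under 0.05. Among protein-coding genes the balance was the other way, with 238 higher and 165 lower of 15049, of which 95 and 57 changed at least 2-fold. This balance turned with protein-coding genes alone (44 higher and 67 lower), at least 1 CPM in 3 libraries (68 and 83), a fold of at least 1.2 (62 and 67), adjusted p under 0.01 (8 and 13) and the Xist term (4 and 13). It also turned without control 2 (16 and 20), control 3 (21 and 39) or RARdn 2 (16 and 31). Groups did not overlap in 27.6% of the genes tested, where chance gives 10%. With a correction for GC content and length the calls were 506 higher and 451 lower (52.9% higher, against 34.2%). The number of calls was 343, 100 and 297 without control 1, 2 and 3, 789 without RARdn 1, 130 without RARdn 2 and 2980 without RARdn 3. It was 111 for protein-coding genes alone and 61 with a term for Xist.

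The sizes of the largest increases depended on single RARdn libraries. After Alb (log2 7.07, 134-fold) came the histone gene copy Hist1h2al, annotated as a processed pseudogene (0.0502 ± 0.0523 and 4.98 ± 3.80 CPM, log2 6.61, adjusted p = 0.0135), Pzp, a plasma protease inhibitor gene (log2 5.05, with 10.2, 3.41 and 0.527 CPM in RARdn 1, 2 and 3), and Ermap, a red cell membrane protein gene (4.30, with 12.4, 1.40 and 1.22 CPM). The smooth muscle genes Cnn1 and Actg2 rose from 0.316 ± 0.139 to 5.77 ± 5.99 CPM (log2 4.202, adjusted p = 0.0271) and from 2.33 ± 0.831 to 14.5 ± 8.65 CPM (2.65, adjusted p = 0.0165). Stra6 and Acpp, an acid phosphatase gene (1.52 ± 0.220 and 10.1 ± 5.80 CPM, log2 2.73, adjusted p = 0.0182), completed the 8. Without RARdn 1 the log2 fold changes of Alb, Pzp and Ermap were 5.27, 3.82 and 2.38, without RARdn 2 those of Cnn1 and Actg2 were 2.88 and 2.04, and without RARdn 3 those of Hist1h2al and Stra6 were 5.91 and 1.89. Without control 1 and control 2 Hist1h2al was at 7.60 and 6.01, and without control 2 Pzp was at 5.95. Actg2 and Pzp lie on chromosome 6 at 83512905 to 83536265 and 128483567 to 128526720, within 40 Mb of Gt(ROSA)26Sor, as does Ret. Leaving out control 2 ended the call of each of these 8 (adjusted p from 0.0539 for Hist1h2al to 0.168 for Ermap), leaving out control 3 that of 7 (not Hist1h2al), leaving out control 1 that of 6 (not Hist1h2al or Actg2) and leaving out RARdn 2 that of 6 (not Cnn1 or Actg2), with adjusted p up to 0.158 for Ermap without control 3. With limma-voom only Actg2 kept its call. Robust dispersions and the test against a fold of 1.2 each ended the calls of Alb, Pzp, Ermap and Stra6.

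Of the 8 largest decreases, 5 were in genes not annotated as protein-coding. Rn7sk, the RNA that holds back the elongation factor P-TEFb (chromosome 9, 78175303 to 78175633), fell from 25.6 ± 1.64 to 0.628 ± 0.461 CPM (log2 -5.23, SE 0.42, adjusted p = 0.00138). Malat1, a nuclear long non-coding RNA (chromosome 19, 5795690 to 5802672), fell from 2325 ± 515 to 216 ± 105 CPM (log2 -3.43, SE 0.39, adjusted p = 0.00631). The ribosomal RNA gene CT010467.1 fell from 9387 ± 143 to 750 ± 89.2 CPM (log2 -3.65, adjusted p = 0.000346). Rps2, a ribosomal protein gene that overlaps Snora64, Snora78 and Snhg9, had log2 -4.83, the microRNA gene Mir6236 -4.74 and Lars2, a mitochondrial leucyl-tRNA synthetase gene, -4.18. Whether reads of other sequences were counted for these 3 was not tested. The mucin gene Muc4, which overlaps Muc20, fell from 9.33 ± 1.40 to 1.06 ± 0.492 CPM (log2 -3.10, adjusted p = 0.00378). The pseudogene BC002163, inside Zbtb20, had log2 -3.20 and lost its call without any 1 library except control 1 (adjusted p from 0.0513 without RARdn 3 to 0.157 without control 2), whereas the other 7 were called without any 1 library.

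By class, the non-coding RNAs that were called were almost all lower. Of 2371 non-coding genes tested, 307 were called lower and 4 higher, and 72.5% had a log2 fold change below 0 (65.8% of lincRNA and 69.6% of antisense genes). TEC genes, transcripts of the annotation that await an experimental check, made up 195 of these decreases against 1 increase among 599 tested, and their median log2 fold change was -1.21. Among lincRNA genes 38 fell and 1 rose of 579, among antisense genes 24 fell and 1 rose of 606, and all 17 called sense intronic genes fell of 68. Protein-coding genes had a median log2 fold change of 0.03, and reads outside genes were lower in 3 of 3 RARdn libraries. The 311 non-coding calls remained in 127, 47 and 163 cases without control 1, 2 and 3 and in 226, 61 and 308 cases without RARdn 1, 2 and 3.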

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

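Among the tests below, those of the library preparation, of GC content and length, of the endocrine share and of the sex of the embryos were chosen after the result was seen, and the test of the host genes was fixed before its outcome was known. Reads that aligned to more than 1 place are outside all comparisons, and their share stood above the highest control (12.5%) by more than the controls' own range in RARdn 2 (14.63%) and RARdn 3 (15.94%), a rule that was set after the shares were seen. The share was 11.1% in RARdn 1, and the groups did not separate (exact permutation p = 0.4).

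The fall of non-coding RNA was weighed against 3 explanations. Among 131 protein-coding genes that hold lowered TEC or sense intronic RNAs on the same strand, the median log2 fold change was -0.068 (95% bootstrap interval over genes -0.116 to -0.0100). That of the RNAs, picked for being called lower, was -4.66. This argues against a matching fall in the hosts' transcript levels, which stand in for transcription here. The interval does not cover the spread between libraries. A correction for GC content and length left 290 of the 307 lower non-coding calls, which argues against such a bias as the whole cause. Of 750 genes in classes that had been seen to fall, 87.73% lay below 0 against 46.1% of protein-coding genes, which a difference in library preparation or input RNA and a fall in the tissue both predict, so this count does not decide between them. Ribosomal RNA genes took 0.930% ± 0.0260 of the counts in controls and 0.0756% ± 0.00549 in RARdn libraries. Neurog3 marks endocrine progenitors, and the pan-endocrine list took 0.214% ± 0.0102 of control counts, against 19.1% ± 0.756 for acinar genes. For ribosomal RNA these values argue against a fall confined to endocrine cells, although list shares do not measure cell numbers. The labels name no batch, so library preparation, input RNA and a fall across the tissue stay open, and a biological fall was not tested.

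The rise of Sst and Hhex with the fall of Ins2 was weighed against 3 explanations. A different endocrine share of the tissue alone would move Sst and Ins2 alike. Their opposite directions were part of the pattern as chosen, so this comparison restates the pattern and is no further test. The log2 ratio of Sst to Ins2 was -3.53 ± 0.0849 in controls and -0.831 ± 0.744 in RARdn libraries, a difference of 2.697. Hhex stayed at 0.5829 (SE 0.16, adjusted p = 0.0391) after scaling to the pan-endocrine list. Correction for GC content and length left Sst at 1.872, Hhex at 0.82 and Ins2 at -0.83, each called. With a term for Xist, which marks the 2 control libraries 1 and 3, Sst was at 2.01 (SE 0.45, against 0.27 before), Hhex at 0.79 (SE 0.22, against 0.13) and Ins2 at -0.82 (SE 0.29, against 0.18), so the sizes held while the errors grew and the calls ended, and a part played by sex cannot be told apart with 1 control of the other kind. A changed balance of delta and beta cell transcripts in RARdn pancreas is a hypothesis that these tables leave open, together with litter, strain and library preparation, which the design does not separate from genotype.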

How the results depend on the processing

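Of 107 named genes and lists under 2037 alternatives, 1613 outcomes kept direction and side of the threshold, 305 lost the call, 52 gained it and 67 changed sign, and none of the 67 was called either way. Protein-coding genes only, GC content and length correction and the Xist term were chosen after seeing the data.

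The 767 changed genes became 2346 without a filter on low counts, 217 with at least 1 CPM in 3 libraries, 403 against a fold of 1.2, 111 with protein-coding genes only, 61 with the Xist term (which spends a degree of freedom), 2245 with DESeq2, 1779 and 58 at adjusted p under 0.1 and 0.01, and 100 to 2980 with 1 library left out. DESeq2 gave no adjusted p for 8905 genes. The number of lists went from 10 to 0 with an estimated correlation. It went to 1 with fry, the list of genes that make, carry or sense retinoic acid, which is not among the 10. With the preset correlation 5 of the 10 (beta cell, other islet hormone, Wnt, mesenchyme and immune) were called in every alternative. The 3 hormone genes became 1 with the CPM filter, 5 with pan-endocrine scaling, 1 with protein-coding genes only, 0 with the Xist term and 0 to 3 with 1 library left out (4 or 5 of 9 at unadjusted p under 0.05). For the sample structure, the first component held 70.92% over the 500 most variable genes and 50.23% to 59.41% with 1 library left out.

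Whether the replicate numbers pair the libraries was not settled. Same-number correlations of deviations were 0.013, -0.014 and 0.126, the last being the highest of all pairs, while control 1 correlated best with RARdn 2 (0.092). With the replicate block 817 genes were called, 632 of them shared.

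Signs changed for results that were not called. With pan-endocrine scaling Gcg was at -0.2155, Iapp at -0.1026 and Ghrl at -0.06224, and with limma-voom Ppy was at -0.007727. With the Xist term Jun was at -0.3258, Ddx3y at -0.02945, Amotl2 at -0.01697, Meis2 at -0.0004191, Cbfa2t3 at 0.05654 and Hbb-bs at 0.02239. With protein-coding genes only Meis2 was at -0.0005159 and Cdh5 at -0.02197, and with at least 1 CPM in 3 libraries Cdh5 was at -0.007427. With GC content and length correction Cdh5 was at -0.03914, Pnliprp1 at 0.0215 and Hbb-bs at 0.07403. Without a filter on low counts Cbfa2t3 was at 0.02967 and Hbb-bs at 0.006454, and Cbfa2t3 was at 0.01617 without the acinar genes and 0.003689 with DESeq2.

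With 1 library left out, log2 fold changes ranged from -0.2493 to 0.1044 for Rarb, -0.02508 to 0.3628 for Iapp, -0.06947 to 0.2272 for Gcg, -0.4872 to 0.6315 for Ppy, -0.2268 to 0.421 for Ghrl, -0.2579 to 0.2046 for Cbfa2t3 and -0.0218 to 0.08187 for Meis2. They ranged from -0.6839 to 0.3407 for Ctrb1, -0.5415 to 0.3749 for Pnliprp1, -0.2212 to 0.02982 for Notch1, -0.223 to 0.358 for Lrrn4, -0.06121 to 0.07107 for Cdh5, -0.2316 to 0.1655 for Hbb-bs, -0.5064 to 0.01928 for Hba-a1, -0.7723 to 0.05455 for C1qa and -0.187 to 0.06877 for Erbb3.

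The direction of 7 lists turned in alternatives. The adjusted p of camera for the endocrine progenitor list was 0.7499 with protein-coding genes only, 0.7512 with GC content and length correction and 0.2113 with the Xist term, 0.0875 by fry with pan-endocrine scaling, and 0.116 to 0.9821 with 1 library left out. For the acinar list it was 0.783 with the replicate block, 0.9908 with protein-coding genes only and 2.073e-16 to 0.863 with 1 library left out, where the lowest was higher in RARdn as in the main test. For the duct and trunk list it was 0.5588 without a filter on low counts. With 1 library left out it ranged from 0.07938 to 0.9971 for that list, 0.00961 to 0.9704 for endoplasmic reticulum stress, 0.1983 to 0.872 for immediate early genes, 0.1221 to 0.9921 for mesothelium and 0.0002857 to 0.872 for the red blood cell list.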

Other observations

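Several called genes outside the fixed lists differed without overlap in all 6 libraries, and all genes in this paragraph were chosen after their values were seen. Bcat1, a branched-chain aminotransferase gene (chromosome 6, 144993835 to 145076184), rose from 1.21 ± 0.242 to 6.75 ± 1.26 CPM (log2 2.48, edgeR adjusted p = 0.00378), and Plbd1 rose from 3.61 ± 0.358 to 13.3 ± 3.52 CPM (1.88, adjusted p = 0.00643). Arntl2, a circadian transcription factor gene (chromosome 6, 146796055 to 146833529), fell from 20.4 ± 1.80 to 4.01 ± 1.75 CPM (log2 -2.33, adjusted p = 0.00713), and Alox5, which makes leukotrienes, fell from 13.1 ± 2.41 to 3.83 ± 0.285 CPM (-1.77, adjusted p = 0.00378). On chromosome 17, the class I histocompatibility gene H2-K1 fell from 132 ± 37.4 to 33.5 ± 14.04 CPM (log2 -1.98, adjusted p = 0.0190), and Gabbr1 rose from 36.2 ± 16.6 to 118 ± 13.9 CPM (1.71, adjusted p = 0.0190). Bcat1, Arntl2, Plbd1 and Alox5 were called without any 1 library, H2-K1 was not called without control 1, control 3 or RARdn 2 (adjusted p = 0.0558, 0.0588 and 0.0714), and Gabbr1 was not called without control 1 or RARdn 2 (0.0657 and 0.0684).

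Gt(ROSA)26Sor, the transcript of a locus widely used for targeted alleles (chromosome 6, 113067428 to 113077333, overlapping Thumpd3 on the other strand), fell from 3.79 ± 0.932 to 0.645 ± 0.0413 CPM (log2 -2.56, SE 0.28, edgeR adjusted p = 0.00543). It was chosen after its values were seen, fell more than 99.2% of 380 long non-coding RNAs of similar level, and lost its call in none of 19 alternatives. Because strain DNA can stay linked to a targeted allele, protein-coding genes within 40 Mb were counted, a distance and a fold chosen after the values were seen: 13 of 438 (2.97%) were called with a fold of at least 2, against 138 of 14586 elsewhere (0.946%, 2-sided Fisher's exact test p = 0.00048). The crowding on chromosome 6 had been seen before this count, so the p describes it and does not test its cause. A candidate explanation is that the allele sits at this locus and brought neighbouring DNA of another strain, which would bear on Ret, Pzp, Actg2, Bcat1, Arntl2, Plbd1 and Alox5. Pzp and Actg2 were uneven among the RARdn libraries, which all carried the allele. In RARdn 1, 2 and 3 Pzp was at 10.2, 3.41 and 0.527 CPM, where Alb was at 597, 137 and 3.19 CPM. Actg2 was at 9.88, 24.5 and 9.18 CPM, where Cnn1 was at 1.85, 12.7 and 2.80 CPM. In a scan of 138 bins of 20 Mb, fixed before its outcome was known though the bin size followed a look at the calls per chromosome, the most crowded bin was on chromosome 17 (11 of 375 genes), and 0.111 of random redraws gave a bin as crowded, so an uneven spread by chance stays open too.

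The 6 libraries can be split in 10 ways into 3 and 3, too few for a share under 0.05. The real split gave 767 changed genes and the highest of the others 2, and it gave 3 hormone genes against 0, so that 1 split of 10 reached each of these counts. Every other split mixed control and RARdn libraries in both of its groups. A difference between control and RARdn then adds to the spread within groups, so their low gene counts do not show what chance gives. Such splits also keep a part of that difference, so their list counts do not measure chance alone. For the gene lists with the preset correlation, 8 of 10 splits gave at least the real 10 lists and the highest gave 15, so chance cannot be excluded for the number of lists, and the list results of camera carry little weight of their own.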
